A study of Homo sapiens with 6 samples.

How the data were processed

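Gene expression was measured on 6 Affymetrix human transcriptome arrays hybridised with RNA of AC16, an established human myocardial cell line. Per the labels, 3 arrays carried RNA of cells exposed to fine particulate matter (PM2.5) at 50 µg/mL for 24 h and 3 carried RNA of control cells. The titles call the arrays of a group biological replicates. No label says whether they came from separate cultures, so p-values measure the spread between these 6 samples, part of which may be technical. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols.

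The deposited values were log2 expression values made with RMA, per the submitters' processing notes. RMA corrects the background, puts the arrays on a common distribution and summarises the probes of a probe set. The version of the software and the genome build were not given in the sources used here, so no coordinates are printed. The table had 70523 rows. The values ran from 2.73 to 19.9, and 264 rows stood at the ceiling of 19.9 on all arrays, so changes in these RNAs could not be measured. Exact repeats of a value also occurred below the ceiling. Of the genes, 33 stood at the ceiling on all arrays, but 55 had the same value on all arrays. GPX4 read 15.913 on all 3 PM2.5 arrays, and the histone gene H2BC5 read 7.21 on PM2.5 replicate 1 and control replicates 1 and 2. Differences in such genes may be understated. The array medians lay between 4.03 and 4.18. A total count has no meaning for arrays, and the number of arrays limits the precision.

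Of 67528 transcript clusters, 23781 had 1 gene symbol, 1543 had several and 42204 were not named in the platform annotation. Control probe sets and clusters with several symbols were left out. For 479 genes with several clusters the cluster with the highest mean over all arrays stood for the gene. This gave 22465 genes. Symbols of 21497 transcript clusters were matched through the gene identifier to the RefSeq table of GRCh38.p14, which changed 0 symbols. The 23 background probe sets read between 3.28 and 5.66. A gene is called above background here when it exceeded 5.66 on at least 3 arrays, which held for 4150 genes, and 17793 genes stayed within background on all arrays. This threshold was set after the data were examined. It is the highest background reading of all, from control replicate 1. On the other arrays the highest background probe set read 4.68 to 5.14, and the median background was 3.86 to 3.92 over all arrays. The threshold is therefore strict, and a gene called within background was not shown to be silent.

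Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no filter on dim genes and no block. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. The same test was run with an estimated correlation, and fry was run beside it. The 35 gene lists, the tests and the rule for naming genes were fixed before the data were examined. At least 5 measured genes were needed, which left out the erythroid list and gave 34 tested lists. By the rule, the text names the genes with the largest changes among those past the test or, with none, the 5 lowest p in each direction. The rule also takes up to 4 genes of each list with the lowest p, but only some of these are named here, and for some lists none. CYP1A1, CYP1B1, HMOX1, NQO1, IL6 and CXCL8 are named whatever their values. MT2A, MT1B and MT1JP, outside this rule, are named as well. Of the 5 lowest-p genes in the lower direction, 1 is not named here. A fixed check of RNA quality, the ratio of 3-prime to 5-prime control signal, was not analysed here, because the control probe sets of the table were not of that kind.

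The arrays fell into 2 sets by the mean of 8 hybridisation and poly-A spike-in probe sets, split at the widest gap. PM2.5 replicate 1 and control replicates 1 and 2 read 10.7 to 10.9 (high spike-in), and PM2.5 replicates 2 and 3 and control replicate 3 read 10.2 to 10.3 (low spike-in). A fit with the array set as a block, and changes within each set, are given beside the results. Within a set 1 array of one group stands against 2 of the other, so these changes carry no error. Further alternatives fixed in advance were the replicate number as a block, centring of arrays, a further quantile normalization, other variance priors, a filter on the dimmest 40% of genes, the mean of a gene's clusters, all transcript clusters, array weights and leaving out each array in turn. Chosen after the data were examined were the array set as a block, the spike-in signal as a covariate, genes above background alone, and protein-coding genes alone after quantile normalization, the last pair also with the array set as a block.

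The test was checked on simulated data with the real gene means and spreads over 22465 genes, 200 of them changed. The changed genes were drawn from those above background and below the ceiling, so the shares recovered do not cover dimmer genes. With no array sets simulated, the fit without a block recovered 31% of 100 genes changed 2-fold, 68% of 50 changed 4-fold and 78% of 50 changed 8-fold, with 6 calls among unchanged genes. With the array sets simulated, the fit without a block recovered 16% of the genes changed 2-fold, 68% of those changed 4-fold and 78% of those changed 8-fold. With the array set as a block these shares were 56%, 84% and 100%, and with no array sets simulated that fit recovered 12%, 50% and 72%. A list of 20 genes above background, all shifted alike, was found in each simulation, and 0 of 30 unchanged lists were called. The simulated noise was drawn separately for each gene, so these lists carried no correlation between genes. In the real data the estimated correlation of the 7 lists called below was 0.07 to 0.40. The simulation therefore cannot show how often such lists are called falsely.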

Results

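The data comprised 6 arrays of the human myocardial cell line AC16, in 2 groups of 3. The comparison asked which genes changed after 24 h with 50 µg/mL PM2.5, the fraction of airborne particles with a diameter of up to 2.5 µm. Values are log2 RMA expression with the SD (n = 3 per group).

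Metallothionein genes were higher after PM2.5. These encode small cysteine-rich proteins that bind zinc, copper and cadmium and are induced by metals. MT1X read 11.5 ± 0.168 (n = 3) after PM2.5 and 9.02 ± 0.775 (n = 3) in controls, a 5.53-fold difference (log2 2.47, SE 0.40). MT1E read 9.48 ± 0.301 against 7.55 ± 1.08 (log2 1.93), and MT1M 6.69 ± 0.439 against 5.53 ± 0.426 (log2 1.16). MT2A stood at the ceiling of the deposited values, 19.9, on all 3 PM2.5 arrays and on 1 control array. The other 2 control arrays read lower, so the size of its difference could not be measured.

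The fixed list of metallothionein and metal response genes rose (limma camera, adjusted p = 5.93e-07), with a median log2 change of 0.26 over 11 measured genes, 9 of which were higher. The call was lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation) and with fry (adjusted p = 0.476), while fry's test for change in either direction gave an adjusted p of 0.00448. Adjusted over the list alone, 4 genes passed in limma (MT1X, MT1G, MT1M and MT1E), and over all genes tested 0 did. All 3 PM2.5 arrays lay above all 3 controls for each of these 4. MT1G, at 5.21 ± 0.0649 against 4.95 ± 0.0480, lay within background on every array. MT1X was 2.32 higher in PM2.5 among the high spike-in arrays and 3.06 among the low spike-in arrays, MT1E 1.37 and 3.15, and MT1M 1.46 and 1.29. MT1E was uneven among the controls, at 6.31 on control replicate 3 against 8.09 and 8.25 on replicates 1 and 2. With the array set as a block the list had a camera adjusted p of 1.26e-05 (adjusted p = 0.790 with an estimated correlation, 0.306 with fry).

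**Figure D1:**
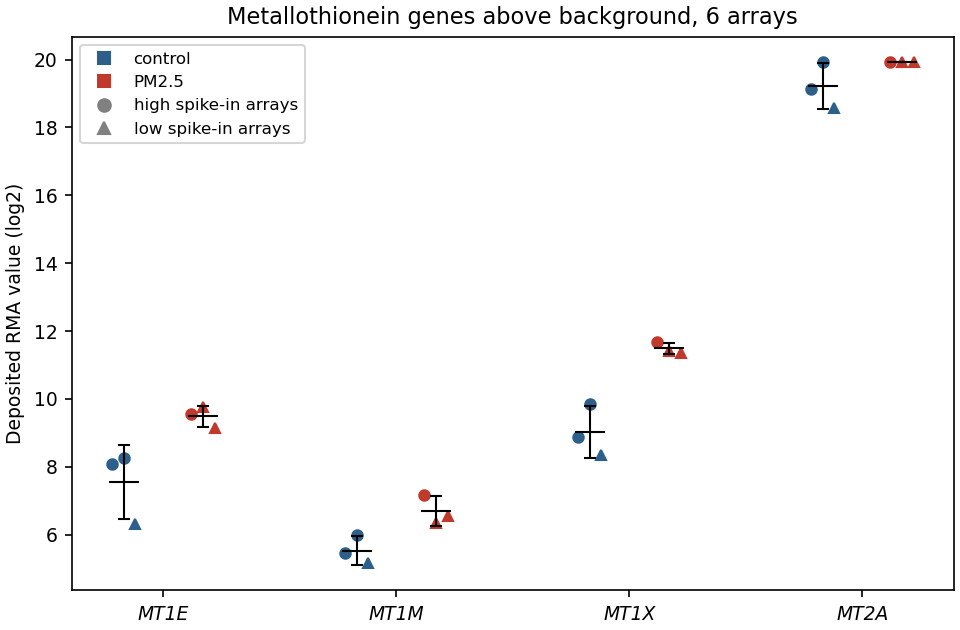
Deposited log2 RMA values of the 4 metallothionein genes of the fixed list that lay above background, on each of the 6 arrays. Colours give the group, symbols the spike-in set, and horizontal bars with whiskers the mean and SD (n = 3); MT1X reads 11.5 after PM2.5 and 9.02 in controls, and MT2A reaches the ceiling of 19.9.

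Over the whole transcriptome, 0 of 22465 genes passed limma's test (lowest adjusted p = 1), and 473 had an unadjusted p under 0.05, 154 higher and 319 lower, where chance gives 1123. With the array set as a block 0 passed again (lowest adjusted p = 0.387), with 1293 at an unadjusted p under 0.05. Among the 4150 genes above background, 136 (3.28%) had groups that did not overlap, 74 higher and 62 lower, against 10% by chance. The genes with the lowest p did not pass. In the higher direction these were MT1X, the metallothionein pseudogene MT1CP (10.04 ± 0.614 against 7.52 ± 0.768), the olfactory receptor gene OR2B6 (3.97 ± 0.0508 against 3.68 ± 0.0228), OR2M1P (4.07 ± 0.0573 against 3.82 ± 0.0656) and the microRNA gene MIR548F5 (4.99 ± 0.222 against 4.40 ± 0.0844). In the lower direction they included MIR378D2 (4.31 ± 0.164 against 5.10 ± 0.244), DNAAF2, a dynein assembly factor (4.15 ± 0.0577 against 4.55 ± 0.120), HDHD5-AS1 (4.13 ± 0.0101 against 4.36 ± 0.0480) and DHFRP3 (3.95 ± 0.0255 against 4.22 ± 0.0323). Of the 10 lowest-p genes, 8 lay within background on every array.

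Of the 34 lists tested, 7 rose and 0 fell by limma's camera at the preset correlation. Besides the metallothionein list these were DNA replication, the unfolded protein and integrated stress response, the NRF2 oxidative stress response and fatty acid synthesis (adjusted p = 0.00981 each), other antioxidant enzymes (adjusted p = 0.0221) and autophagy and lysosome (adjusted p = 0.0495). With an estimated correlation 0 of the 7 held (adjusted p = 0.893 with an estimated correlation for these 6), and fry called 0. The shifts were small. The median log2 change was 0.08 over 34 DNA replication genes, 0.08 over 23 stress response genes, 0.06 over 22 NRF2 genes, 0.18 over 8 fatty acid synthesis genes, 0.04 over 18 antioxidant genes and 0.05 over 26 autophagy and lysosome genes. Adjusted over the list alone, 0 genes of any of these 6 lists passed in limma. The arrays of the low spike-in set carried more protein-coding signal, and 2 of the 3 PM2.5 arrays but 1 of the 3 control arrays belonged to it. Within the low spike-in arrays the medians of these 6 lists were -0.06, -0.09, -0.02, -0.08, -0.05 and -0.12 in the order of the medians above, and within the high spike-in arrays they were 0.06, 0.12, 0.01, 0.15, 0.06 and 0.03. With the array set as a block none of the 6 passed (adjusted p between 0.296 and 1.00). The count of 7 higher and 0 lower lists became 1 higher and 1 lower without PM2.5 replicate 2, 1 higher without PM2.5 replicate 3, 2 higher and 1 lower without control replicate 1, 1 higher and 1 lower without control replicate 2 and 13 higher and 1 lower without control replicate 3. The lower list was that of epithelial markers without control replicate 3 and mitosis otherwise. After centring each array on its median 1 list, metallothionein, passed.

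HMOX1, the inducible haem oxygenase, read 6.39 ± 0.110 after PM2.5 and 6.07 ± 0.128 in controls, and NQO1, a quinone reductase, 14.9 ± 0.172 against 14.4 ± 0.640. Neither passed (log2 change 0.32 and 0.48, limma adjusted p = 1 each). The groups did not overlap for HMOX1 and overlapped for NQO1. Among the high and the low spike-in arrays the change was 0.46 and 0.22 for HMOX1, and 0.62 and -0.08 for NQO1. GPX1, which reduces peroxides, read 9.92 ± 0.211 against 9.34 ± 0.107, so that the groups did not overlap, and did not pass. DDIT4, a stress-induced inhibitor of growth signalling, read 7.10 ± 0.0531 against 6.87 ± 0.111, also without overlap. HERPUD1 read 8.89 ± 0.225 against 8.52 ± 0.407, with overlap, and ATF3 stayed within background. POLA2, a subunit of DNA polymerase alpha, read 7.85 ± 0.102 against 7.62 ± 0.141. FASN, the fatty acid synthase, read 8.99 ± 0.185 against 8.54 ± 0.877, SREBF1 6.41 ± 0.0571 against 6.23 ± 0.147, and CTSD, a lysosomal protease, 12.02 ± 0.0649 against 11.8 ± 0.215.

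**Figure D2:**
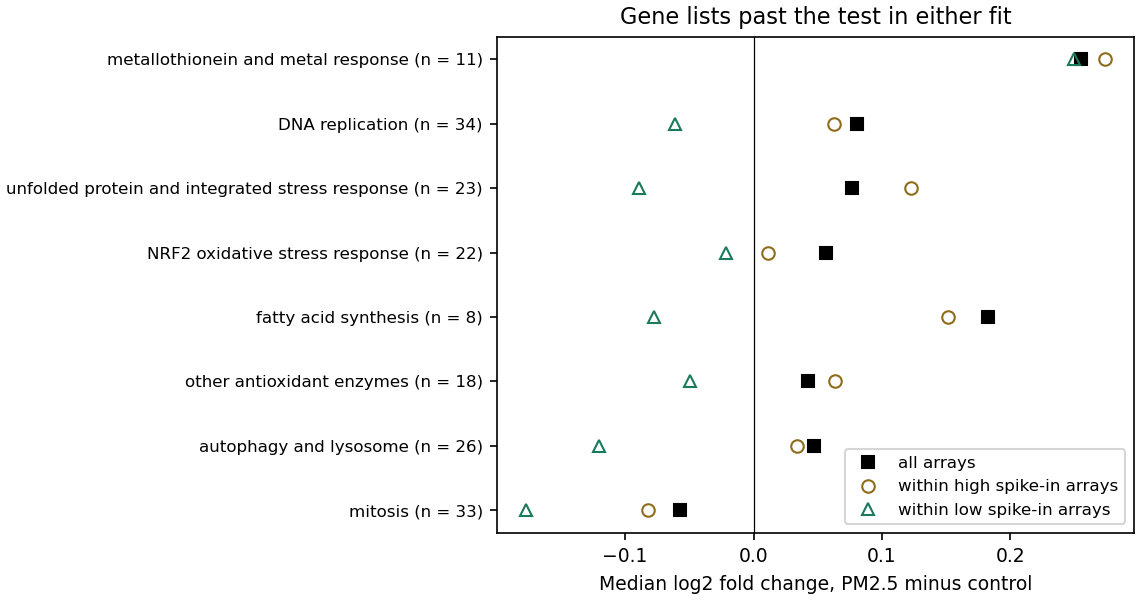
Median log2 change (PM2.5 minus control) of the 8 gene lists that passed limma's camera without or with the array set as a block, with the number of measured genes. Squares use all arrays, circles the high and triangles the low spike-in arrays; the metallothionein list lies above 0 in both sets, the mitosis list below 0 in both, and the other 6 lists below 0 among the low spike-in arrays.

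The mitosis list was called lower with the array set as a block, at camera's preset correlation. The list had a median log2 change of -0.06 over 33 genes and did not pass (camera adjusted p = 0.0912, adjusted p = 0.893 with an estimated correlation). With the array set as a block the median was -0.12 (camera adjusted p = 8.66e-05, adjusted p = 0.790 with an estimated correlation and 0.306 with fry). The medians were -0.08 among the high and -0.18 among the low spike-in arrays. Among its 18 genes above background the median was 0.02 without the block and -0.12 with it. Tested among genes above background, the list passed in neither fit (camera adjusted p = 0.817 and 0.293). It passed in 8 of 21 alternatives. Adjusted over the list alone, 0 of its genes passed in limma with or without the block. NDC80, a kinetochore component, read 4.95 ± 0.144 against 5.26 ± 0.119, DLGAP5 5.16 ± 0.0849 against 5.33 ± 0.0228, NUF2 4.96 ± 0.216 against 5.21 ± 0.0342 and HMMR 4.83 ± 0.0289 against 4.96 ± 0.0747, all within background.

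Above background lay 2 of 11 AhR targets, 4 of 28 NF-kB inflammatory mediators and 2 of 25 interferon response genes, and the fixed genes CYP1A1, CYP1B1, IL6 and CXCL8 lay within background on every array. CYP1A1 and CYP1B1, enzymes induced through the aryl hydrocarbon receptor, read 4.16 ± 0.0744 against 4.09 ± 0.0436 and 4.08 ± 0.102 against 4.04 ± 0.0594. IL6 read 4.93 ± 0.135 against 4.87 ± 0.0315, and CXCL8 4.29 ± 0.0805 against 4.197 ± 0.0521. No member of these lists passed limma's test adjusted over the list alone. The lists of AhR targets (median log2 change -0.0064, camera adjusted p = 0.708), NF-kB inflammatory mediators (-0.02, adjusted p = 0.936), interferon response (-0.0099, adjusted p = 0.708), MAPK immediate early genes (-0.0061, adjusted p = 0.708), p53 targets (-0.02, adjusted p = 0.525), apoptosis regulators (-0.0064, adjusted p = 0.855) and heat shock (-0.0048, adjusted p = 0.836) did not pass. For the AhR, NF-kB, apoptosis and heat shock lists the median lay below 0 while camera's direction was up. CCL2, a monocyte chemokine, read 5.77 ± 0.0269 against 6.15 ± 0.344, and HSPA1A 8.86 ± 0.104 against 8.35 ± 0.540. IFIT1 read 3.58 ± 0.0759 against 3.81 ± 0.0756, within background on every array. MDM2 read 5.49 ± 0.0189 against 5.68 ± 0.0911 and exceeded background on 2 arrays only.

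The further lists of metabolism, matrix and heart function did not pass in the main comparison. Their camera adjusted p was 0.708 for cholesterol synthesis (median log2 change 0.05), 0.466 for fatty acid oxidation (0.0027), 0.855 for oxidative phosphorylation (0.01), 0.860 for hypoxia and glycolysis (0.00), 0.540 for gap junction and adhesion (0.02), 0.306 for extracellular matrix and fibrosis (0.01), 0.471 for matrix metalloproteinases (0.02) and 0.358 for coagulation and vascular mediators (-0.03). Without control replicate 3 the lists of cholesterol synthesis (adjusted p = 0.00988), oxidative phosphorylation and gap junction and adhesion (0.0128 each) and extracellular matrix (0.00194) passed as higher. The last also passed, higher, without PM2.5 replicate 1 (0.0165), and the last 3 with array weights (0.00430, 0.0328 and 0.0206). Fatty acid oxidation passed as higher among genes above background (0.0149). With the spike-in signal as a covariate cholesterol synthesis (0.00636), oxidative phosphorylation (0.00127), gap junction and adhesion (0.0133) and extracellular matrix (0.0358) passed as lower. BGN, the matrix proteoglycan biglycan, read 11.7 ± 0.249 against 10.8 ± 0.666 and its groups overlapped. The sarcomere list (-0.02) and the lists of calcium handling and ion channels (-0.0049, with camera's direction up) and of cardiac transcription factors and stress hormones (0.02) had an adjusted p of 0.708 each. Above background lay 0 of 12 cardiac transcription factor and stress hormone genes and 4 of 21 sarcomere genes, among them DES, the muscle intermediate filament desmin (7.01 ± 0.342 against 7.32 ± 0.364).

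Lists of cell type markers gave no call in the main comparison. The camera adjusted p was 0.471 for fibroblast markers (median 0.02), 0.471 for smooth muscle markers (-0.03), 0.323 for endothelial markers (0.01), 0.522 for macrophage and leukocyte markers (0.00069) and 0.306 for epithelial markers (-0.05). Epithelial markers passed, lower, without control replicate 3 (adjusted p = 0.0312), and endothelial markers passed, higher, with the spike-in signal as a covariate (adjusted p = 0.0200). Above background lay 3 of 11 fibroblast, 2 of 8 smooth muscle, 0 of 10 endothelial, 1 of 12 leukocyte and 2 of 9 epithelial genes. The epithelial pair was KRT18 (14.5 ± 0.0727 against 14.6 ± 0.181) and KRT8 (14.7 ± 0.561 against 15.0 ± 0.235), keratins also made by many cultured lines. Both measured erythroid genes, HBB and ALAS2, lay within background and their list was too short to test. Among lists that mark RNA quality, the adjusted p was 0.540 for replication-dependent histones, 0.323 for cytosolic ribosomal proteins and 0.320 for reference genes. The ribosomal protein and reference lists passed, higher, without PM2.5 replicate 1 (adjusted p = 0.00482 and 0.0186), without control replicate 3 (0.00227 and 0.0165) and with array weights (0.000199 and 0.00688). With the spike-in signal as a covariate the ribosomal protein list passed as lower (0.0133) and the histone list as higher (0.0290).

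The arrays resembled each other by spike-in set more than by treatment. Over the 4150 genes above background, arrays of different groups in the same set correlated at 0.991 to 0.996, and arrays of the same group in different sets at 0.945 to 0.977 (Pearson's r across genes, which are not independent replicates). Component 1 held 82.5% of the variance and separated the sets, and component 2 held 8.30%. On component 2 the PM2.5 arrays lay at -7.93, -0.75 and -9.60 and the controls at -0.20, 8.56 and 9.93, so the groups did not overlap, with PM2.5 replicate 2 and control replicate 1 close to each other. Small nucleolar RNAs, which guide the modification of ribosomal RNA, differed most: the median difference of 144, low minus high spike-in set, was -1.62 on the log2 scale, and 135 of them were lower in the low set. Protein-coding genes moved the other way, by 0.25 in the median of 3447. In limma 1810 genes differed between the sets at an adjusted p under 0.05, 596 lower and 1214 higher in the low set. The mean of small nucleolar RNAs was 11.3 ± 0.750 (n = 3) after PM2.5 and 12.003 ± 0.989 (n = 3) in controls (exact permutation test, two-sided, p = 0.300, where 0.1 is the smallest p that 3 against 3 arrays allow). No array duplicated another.

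**Figure D3:**
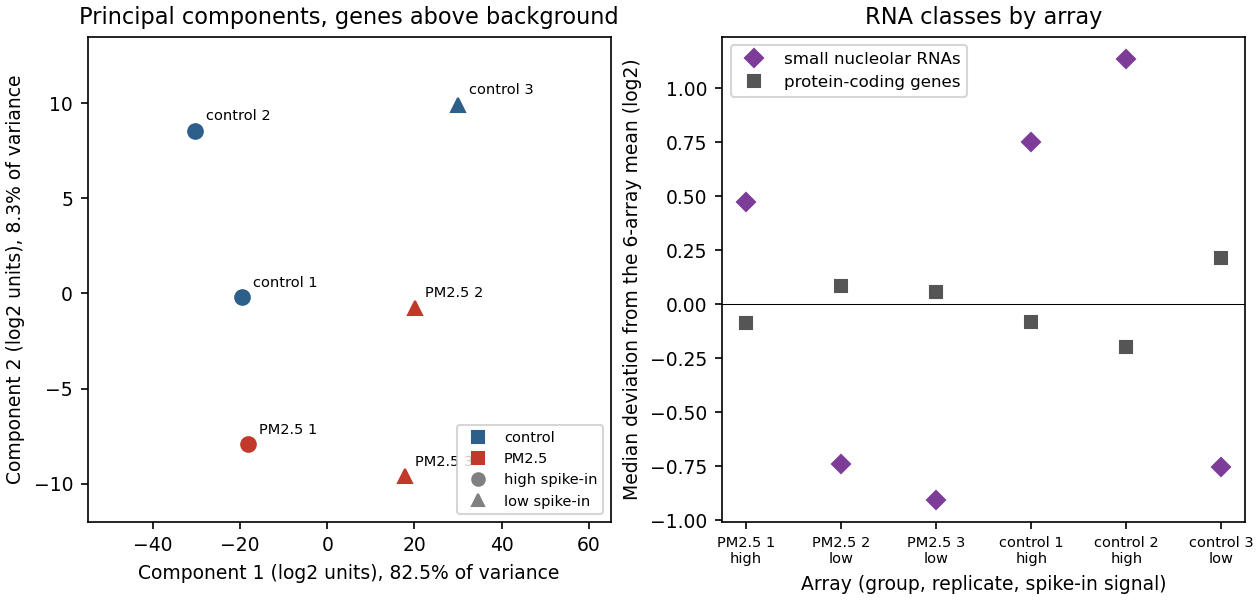
Left, the arrays on the first principal components of the 4150 genes above background (log2 units), coloured by group with symbols for the spike-in set. Right, the median deviation of 144 small nucleolar RNAs and 3447 protein-coding genes from their means over the 6 arrays (log2); the 3 high spike-in arrays lie above 0 for small nucleolar RNAs and the 3 low spike-in arrays below.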

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

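The array set and spike-in fits, the background filter and the protein-coding normalization were chosen after the data had been seen; the other alternatives were planned. The count of changed genes was 0 in limma under all 21 alternatives, leaving out each array in turn among them. Between 35 (of 4150 genes above background) and 6517 (of 22465 genes, array weights) had an unadjusted p under 0.05. The array weights ran from 0.226 for control replicate 3 to 6.025 for control replicate 1, so that fit leaned on control replicate 1. Of 684 results of single lists, 575 stayed on their side of the threshold, of which 99 turned direction without being called in either fit; 68 lost a call, 27 gained a call and 14 turned direction with a call in at least 1 of the fits. Of 2706 values of single named genes, 0 passed and 77 changed sign. The metallothionein list passed in 17 of 19 alternatives (adjusted p 3.68e-08 to 0.863) and was not tested among genes above background, where 4 of its members were left. The 6 other lists of the main comparison passed in 7 to 10 of 21, in either direction, and none passed with the array set as a block. The 8 passes of autophagy and lysosome include the fit with the spike-in signal as a covariate, where the list was lower. A robust variance prior and all transcript clusters were not run for lists. The cause of the changes below was not tested.

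Of lists past the test (7 higher and 0 lower as first analysed), centring the arrays gave 1, higher. A fit without the intensity trend gave 1 lower besides. Array weights gave 12, all higher, and camera with an estimated correlation and fry gave 0. The array set as a block gave 2, 1 higher and 1 lower, and 1 higher among genes above background, which was the histone list. Protein-coding genes alone gave 2, 1 higher and 1 lower, without and with the array set as a block. The spike-in signal as a covariate gave 3 higher and 7 lower. Leaving out an array gave 1 to 14 lists in total, 1 to 13 higher and 0 to 1 lower.

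With the spike-in signal as a covariate these lists turned from higher to lower: NRF2 (adjusted p 0.290), other antioxidant enzymes (0.890), unfolded protein and integrated stress response (0.567), DNA replication (0.05001), cholesterol synthesis (0.00636), fatty acid synthesis (0.890), oxidative phosphorylation (0.00127), autophagy and lysosome (0.00127), gap junction and adhesion (0.0133), extracellular matrix and fibrosis (0.0358) and cytosolic ribosomal proteins (0.0133). The autophagy and lysosome list also turned with the array set as a block (0.296), with that block among protein-coding genes (0.796) and without control replicate 2 (0.887), in a range of 3.10e-06 to 0.887 when leaving out an array.

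Whether the replicate numbers pair the arrays could not be told. Deviations from the group means of same-numbered arrays correlated at 0.779, -0.654 and 0.773. All pairs of a PM2.5 and a control array correlated at 0.773 to 0.834 within a spike-in set and negatively across sets. The arrays of replicates 1 and 3 share a set and those of replicate 2 do not, so the values follow the sets. With the replicate number as a block, 0 genes and 7 lists passed, and the 7 lists were the same 7. For low signal, 17793 genes within background on all arrays limit what can be seen.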

Other observations

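The checks of explanations in this part were chosen after the results had been seen. Results of the planned tests are repeated beside them. Metallothionein relatives outside the fixed list, picked after the pattern was seen, had higher means in PM2.5, and none passed limma's test over all genes (adjusted p = 1 each for MT1CP, MT1JP and MT1B). MT1CP, MT1JP and MT1B read 10.04 ± 0.614, 9.39 ± 0.704 and 7.001 ± 0.460 (n = 3) after PM2.5 and 7.52 ± 0.768, 7.14 ± 1.16 and 5.68 ± 0.565 (n = 3) in controls. MT1CP and MT1JP are pseudogenes. Of 7 metallothionein transcripts above background, 6 had every PM2.5 array above every control array. Among the controls, MT1B and MT1M exceeded background on replicate 2 only, so the filter favoured transcripts high in PM2.5. These transcripts also varied together, as given below, so they do not count as separate results.

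The metallothionein difference was weighed against the array set, which is not balanced between the groups. The median difference of the 4 listed genes above background, with MT2A, which reached the ceiling, taken as read, was 1.42 among the high and 2.21 among the low spike-in arrays. Over all 11 measured genes of the list it was 0.27 and 0.25. Each set holds a single array of one group, so these differences carry no error. Within that limit the smaller value for the 4 genes, 1.42, argues against the array set as the whole source of their difference. Signal of 1 gene read by probes of its near-identical relatives stays open: deviations from the group means over 6 transcripts correlated at a median of 0.842 (0.528 to 0.966), which is neither near identity nor low. A candidate explanation is a response to metals carried by the particles, which was not tested because no metal was measured.

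The arrays fell into 2 sets that cross the treatment, with small nucleolar RNAs moving against protein-coding genes. The change from the high to the low spike-in set of small nucleolar RNAs, minus that of protein-coding genes at the same signal level, had a median of -2.08 on the log2 scale, and 99 of 99 lay below the protein-coding median. This argues against a difference in signal range alone, under which this value would lie near 0. It is consistent with a different balance of small structured RNA and messenger RNA in the labelled material, which may come from RNA extraction or amplification. Exchanged labels of PM2.5 replicate 1 and control replicate 3 would make the sets coincide with the groups, the split that gave 2231 genes and 16 lists. In the labels as given 3 metallothionein genes of the fixed list above background, and 6 of the 7 metallothionein transcripts above background, separated the groups, but no response known from outside these arrays was at hand, so an exchange cannot be told apart from the labels as given.

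The lower mitosis list with the array set as a block was weighed against a general fall of messenger RNA signal in that fit. The 10000 random protein-coding lists matched on signal level had a median of -0.03, so such genes did fall slightly in that fit. Of these lists, 0.01% had a median as low as -0.12, which argues against this general fall as the whole source. The mitosis list was picked because it passed in that fit, and the share makes no allowance for this choice. The random lists do not carry the correlation between mitosis genes. Among genes above background with the same block the list did not pass (camera adjusted p = 0.293), with a median of -0.12 there too. Its adjusted p ran from 9.65e-06 to 0.997 over its alternatives. No biological explanation was tested.

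The 10 splits of the 6 arrays into 3 against 3 are too few for a share under 0.05. The real split gave 0 changed genes, so that 10 of 10 splits gave as many was fixed in advance and tests nothing. The highest other gave 2231. That split followed the array sets and points to a structure of the samples. In lists past the test, 6 of 10 splits gave at least as many as the 7 of the real split, and the highest other, again the split by array set, gave 16. With the array set as a block 0 genes and 2 lists passed, and 0 lists passed in that fit with an estimated correlation or with fry.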
